A study of Mus musculus with 6 samples.

How the data were processed

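RNA from 6 mouse tumour samples of MC38, a colon carcinoma cell line of mouse origin, was sequenced as stranded mRNA libraries. Per the labels, RNA was taken with TRIzol, and the samples form 2 groups of 3, 1 given phosphate-buffered saline (PBS) and 1 given Ms-PDL1scfv-IL15, a Mycobacterium smegmatis strain engineered to make an immunocytokine that joins an antibody fragment against PD-L1 to the cytokine IL-15. The labels call the samples replicate biosamples and do not say whether each came from a separate mouse, so p-values measure the spread between these samples. Per the submitters' processing notes, fastp 0.23.4, STAR 2.5.3a and featureCounts were used, and the genome builds GRCh38 and mm10 are both named without a role. The positions in the deposited count table are those of mouse mm10, and coordinates below are given in that build. The annotation release, the strand setting of the counting and any use of molecular identifiers are not given in the sources used here.

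The authors deposited 1 table of raw counts for 49492 genes, not normalized, with 1 column per library. The columns of the treated group carry a short form of the sample title, and they were matched by that name and the replicate number. Total counts were between 49714494 and 62727290 per library. Low counts were mostly even: of the genes with 1 to 4 counts in a library 72.2% on average had an even count, against 50 expected, and 66.8% of those with 5 to 20 counts. The deposited counts therefore appear to hold both mates of most read pairs, so that 1 fragment adds 2 counts. Counts were tested as deposited, and halved counts were an alternative. The floor below which no fold was given was 3 fragments, that is 6 counts, over a group, and ratios against 1 to 3 fragments carry a 95% interval (exact binomial) from halved counts. Intervals and floors cover counting error only. Before any averaging, every pair of libraries was compared, and all pairs differed by more than sampling noise, with a chi-square per degree of freedom of at least 12.4.

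Genes were kept with edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15), which left 18775 genes. Of their symbols 18172 were found in GENCODE annotation of the same build. Library sizes were scaled by TMM, and the 2 groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust dispersions, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Log2 fold changes are treated over PBS, with a standard error (SE) derived from the F statistic. CPM values are relative to the TMM-scaled library size, as mean ± SD with n = 3 libraries per group. Genes without a called change are given with their values only.

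The 37 gene lists, chosen for tumour cells, immune cells and responses, stroma and neighbouring tissues, were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. Lists hold 645 symbols in all, counted once each, of which 586 were tested. For 2 symbols an older name was used, and 1 symbol was not matched. Each list with at least 5 kept genes was compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 37 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. Per-gene p-values were also adjusted over each list alone. The named genes were up to 10 called genes per direction with the largest change (there were none), 2 members with the smallest p of each called list, and 15 genes named in advance. Of these, 1 list member is not reported here. Genes outside this rule are said to have been chosen after their values were seen. The mitochondrial share of counts was compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1.

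The tests were checked on counts simulated from the means and library sizes of this comparison over 18775 genes. Each gene was drawn independently, so members of a list were uncorrelated in the simulation. In the data the estimated correlation was, for example, 0.78 between type I interferon genes and 0.03 between NK genes. The simulation therefore cannot show how camera with the preset correlation behaves on lists of correlated members. Apart from the T cell list, changed genes were drawn only from those with a mean of at least 1 CPM. Recovery of rarer genes was therefore not measured. No shift shared by many genes in 1 library, as in treated replicate 1, was simulated. Of 100 genes changed by 1 on the log2 scale edgeR recovered 78%, and of 100 changed by 2 it recovered 94%. It made 14 false calls and 1 call in the raised T cell list among 187. DESeq2 1.42.0 recovered 89% and 96%, with 41 false calls and 2 calls in that list among 228. With no gene changed, edgeR made 1 call and DESeq2 made 32. With the T cell list raised by 0.5 on the log2 scale, camera called it at an adjusted p of 1.5e-08 with the preset correlation and gave an adjusted p of 0.0978 with an estimated one, while fry called it (adjusted p = 0.0297). With nothing changed, camera with the preset correlation called 2 of 37 lists.

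Alternatives were other scaling factors, no filter and a stricter filter (at least 1 CPM in 3 libraries), a block for the replicate number, each library left out in turn, non-robust dispersions, removal of the 10 most abundant genes or of immunoglobulin and T cell receptor genes, DESeq2, limma voom with and without sample weights, a minimum absolute log2 fold change of 1, and other list tests. Covariates for adipocyte or muscle markers, the fit without both libraries numbered 1, and halved counts were added after the data were seen. No column of the table was left out.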

Results

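The series compared the transcriptome of subcutaneous MC38 tumours after Ms-PDL1scfv-IL15 with that of tumours given PBS, to ask which molecular changes accompany the antitumour response to the engineered bacterium. Each group held 3 libraries. Total counts were 53019163, 58456659 and 49714494 in PBS replicates 1 to 3 and 62727290, 52328993 and 57576868 in treated replicates 1 to 3. Mitochondrial genes took 1.01% ± 0.080 of counts in treated libraries and 0.877% ± 0.038 in PBS libraries (SD, n = 3), with every treated library above every PBS library (exact permutation test, two-sided, p = 0.1, the smallest this design allows).

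The libraries differed in how much transcript of neighbouring tissues they held. Skeletal muscle markers stood on average 5.36 on the log2 CPM scale above the PBS mean in treated replicate 1, against 1.44, −0.42 and −1.02 in PBS replicates 1 to 3 and −1.11 and 0.75 in treated replicates 2 and 3. Actn3, the fast-fibre α-actinin, had 46.5 CPM in treated replicate 1 and 0.379 and 0.889 in treated replicates 2 and 3. Adipocyte markers stood at 2.51 and 3.00 in treated replicates 2 and 3, at 0.11 in treated replicate 1, and at 1.5, −0.76 and −0.73 in PBS replicates 1 to 3. Lpl, which encodes lipoprotein lipase, had 33.5 ± 18.2 CPM in treated and 9.60 ± 7.20 in PBS libraries (n = 3). Both lists were called higher in treated tumours by camera with the preset correlation, muscle markers with a median log2 fold change of 3.38 (adjusted p = 0.0073) and adipocyte markers with 1.80 (adjusted p = 0.000149), with adjusted p = 0.679 and 0.541 with an estimated correlation. All 19 measured muscle and all 13 adipocyte markers had positive values, and 0 of either list passed when adjusted over the list alone. Without treated replicate 1 the muscle median was −0.42 and the call was lost. It was also lost without PBS replicate 3 (median 2.93, adjusted p = 0.0686), without both libraries numbered 1 (0.84) and in voom with sample weights (0.90), and without PBS replicate 1 the adipocyte median was 3.54.

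No single gene passed the threshold between treated and PBS tumours, and innate and inflammatory gene lists were called higher in treated tumours by camera with a preset correlation. With an estimated correlation 0 lists were called (adjusted p from 0.446), and fry called 0 in a direction. Fry's mixed test, which asks for change in either direction, called 3 lists. They were lymphoid (adjusted p = 0.00313), NK (0.00527) and pattern recognition genes (0.0408). By edgeR's quasi-likelihood test 0 genes were higher and 0 lower among 18775 at an adjusted p under 0.05, the smallest adjusted p being 0.0978. At an unadjusted p under 0.05 there were 2518 genes, 1492 higher and 1026 lower, against 938.75 given by chance, and in 18.8% of genes the groups did not overlap, against 10% by chance. Of these non-overlapping genes 1739 were above and 1799 below PBS in treated libraries. DESeq2 called 531 genes higher and 142 lower, and limma voom 0 and 0. The edgeR count rested on treated replicate 1, the library rich in muscle transcripts: without it 448 genes were called higher and 210 lower, of which 373 were also called by DESeq2. Treated replicate 1 also had the lowest adipocyte marker mean of the treated group. Without a filter on low counts edgeR called 104 higher and 36 lower, and 137 of these 140 genes were among those kept by the filter.

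By camera with the preset correlation, 23 of the 37 gene lists were higher in treated tumours and 0 lower. With an estimated correlation the adjusted p ran from 0.446 to 0.679 over these 23 lists. In 11 of the 23 the list mean of every treated library lay above that of every PBS library (exact permutation test, two-sided, p = 0.1, the smallest this design allows). The calls therefore hold against other genes under a low preset correlation, and not in camera's mode with a correlation estimated from these 6 libraries. Correlation between members need not be the whole reason for the loss. NK genes, with an estimated correlation of 0.033, went from a camera adjusted p of 0.00202 to 0.446. The simulated T cell list, with uncorrelated members, went from 1.5e-08 to 0.0978.

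**Figure D1:**
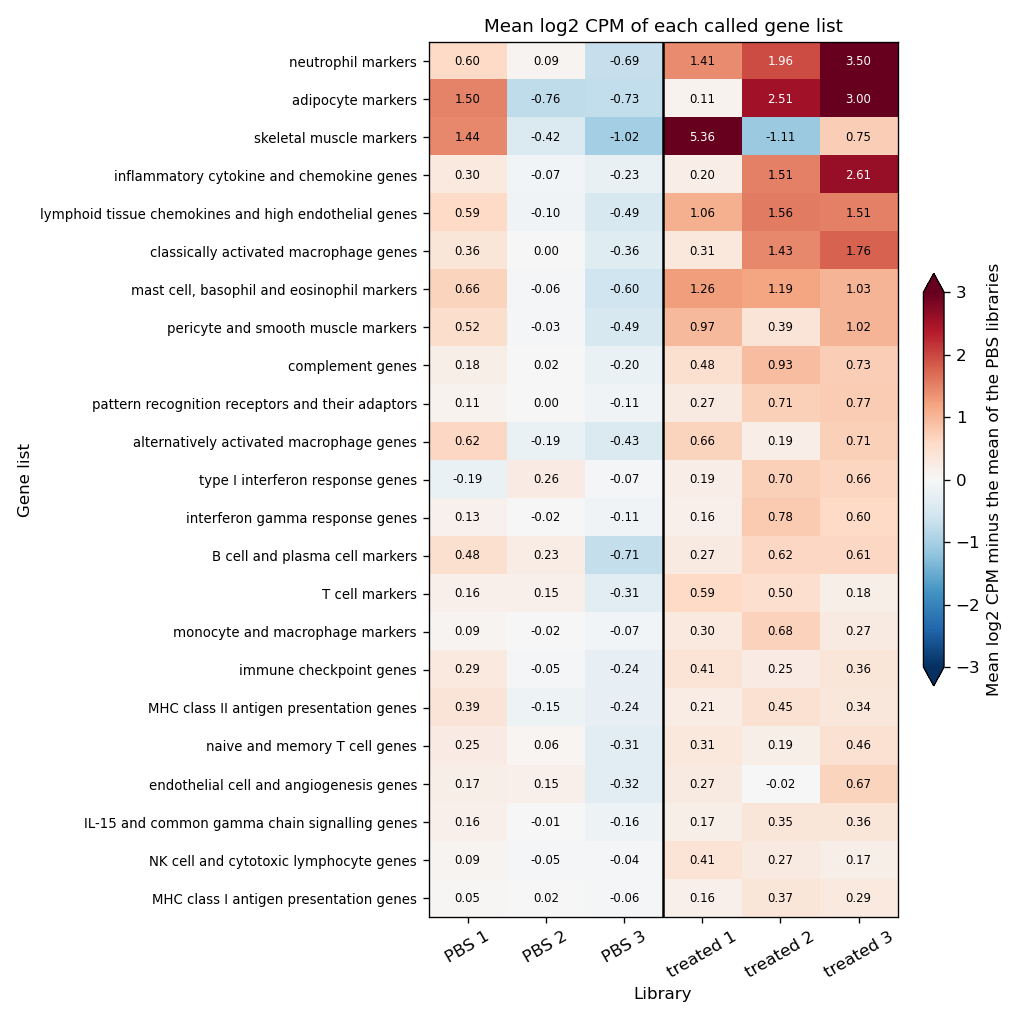
Mean log2 CPM of the members of each of the 23 gene lists called higher in treated tumours (vertical axis), in each of the 6 libraries (horizontal axis), relative to the mean of the PBS libraries; colours span −3 to 3 and each cell prints its value. Neutrophil markers lay at 1.41, 1.96 and 3.50 in the treated libraries, while skeletal muscle markers stood out in treated replicate 1 at 5.36 and adipocyte markers in treated replicates 2 and 3 at 2.51 and 3.00.

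Interferon response lists were called higher with the preset correlation. All 24 type I interferon response genes had positive values, with a median log2 fold change of 0.49, as did all 24 interferon gamma response genes, with a median of 0.53. Camera gave adjusted p = 1.8e-10 and 4.3e-10, with adjusted p = 0.446 for both with an estimated correlation. Adjusted over the list alone, 10 of the type I and 12 of the interferon gamma genes passed, and 0 passed when adjusted over all genes tested. Bst2 (tetherin, which holds virions at the cell surface; chromosome 8, 71534255 to 71537456) had 70.2 ± 9.46 CPM in treated and 50.4 ± 2.51 in PBS libraries (SD, n = 3), a log2 fold change of 0.48 ± 0.10 (SE, adjusted p = 0.166). Oasl1, of the oligoadenylate synthetase-like family, had 0.80 ± 0.17. Irgm2 and Igtp, interferon-inducible GTPases that act against intracellular microbes, had 0.46 ± 0.08 and 0.49 ± 0.10. The genes Irgm2 and Igtp overlap on chromosome 11 (58199618 to 58222782 and 58199556 to 58207591), so their counts are not independent. Type I list means were 0.19, 0.70 and 0.66 in treated replicates 1 to 3 and −0.19, 0.26 and −0.07 in PBS replicates 1 to 3, so treated replicate 1 lay below PBS replicate 2. Interferon gamma means were 0.16, 0.78 and 0.60 in treated replicates and at most 0.13 in PBS libraries. In both lists the lowest treated value was in the library with most muscle and least fat transcript of the treated group. For comparison, 10 general leukocyte genes were all positive, with a median log2 fold change of 0.42.

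Antigen presentation, pathogen sensing and complement genes showed the same direction. All 19 genes of MHC class I presentation were positive with a median of 0.26, 12 of them passing when adjusted over the list alone. H2-T23, which encodes the non-classical molecule Qa-1, had 115 ± 12.5 CPM in treated and 81.5 ± 4.33 in PBS libraries, and a log2 fold change of 0.50 ± 0.09 (adjusted p = 0.156). H2-Q7 had 0.55 ± 0.11, and reads of such near-identical H2 genes can be shared between copies. Of 23 pattern recognition receptors and adaptors 22 were positive, with a median of 0.54 and 15 passing over the list alone. Nod1, a cytosolic sensor of bacterial peptidoglycan (chromosome 6, 54923949 to 54972612), had 25.6 ± 4.35 CPM against 16.0 ± 0.820 and a log2 fold change of 0.68 ± 0.12 (adjusted p = 0.157). Fcer1g, the signalling chain shared by several lectin and Fc receptors, had 0.64 ± 0.12. All 16 complement genes were positive with a median of 0.45, 8 passing over the list alone. C4b had 86.7 ± 15.4 CPM against 43.7 ± 6.17, and C1s1, a protease of the classical pathway, 255 ± 57.6 against 125 ± 15.3. MHC class II genes were positive in 10 of 12 with a median of 0.38, 2 passing over the list alone, Cd86 (0.55 ± 0.12) and Ctss, the protease that trims the invariant chain (0.61 ± 0.14). Camera adjusted p-values were 1.3e-08 for class I, 1.8e-10 for pattern recognition, 1.3e-07 for complement and 0.000594 for class II, and with an estimated correlation adjusted p = 0.446 for the first 3 lists and 0.541 for class II. Over all genes tested 0 members passed. Adipocyte markers were also higher in treated replicates 2 and 3, and with their mean as a covariate the class II call ended (median 0.11, adjusted p = 0.276). Class II means overlapped, PBS replicate 1 (0.39) lying above treated replicates 1 and 3 (0.21 and 0.34), and without PBS replicate 1 the median was 0.59. The 10 general leukocyte genes had a median of 0.42.

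Neutrophil and inflammatory genes had the largest median log2 fold changes of the immune lists. All 14 measured neutrophil markers were positive, with a median log2 fold change of 2.22, and 6 passed when adjusted over the list alone. Csf3r, the receptor for the granulocyte growth factor G-CSF (chromosome 4, 126024550 to 126044440), had 11.4 ± 5.69 CPM in treated and 2.75 ± 0.450 in PBS libraries (SD, n = 3), a log2 fold change of 2.05 ± 0.41 (adjusted p = 0.199). S100a8, a calcium-binding protein of neutrophil granules and cytosol, had 0.57, 1.35 and 4.60 CPM in treated replicates 1 to 3 and 0.0836 ± 0.0768 in PBS libraries. Of 23 inflammatory cytokines and chemokines 22 were positive, with a median of 1.92, yet 0 passed over the list alone. Tnf had 2.32, 4.13 and 6.60 CPM in treated replicates 1 to 3 and 1.88 ± 0.306 in PBS libraries, and Lif had 7.20 ± 2.68 against 3.78 ± 0.392. The inflammatory list mean was 0.20, 1.51 and 2.61 in treated replicates 1 to 3, so treated replicate 1 lay within the PBS range of −0.23 to 0.30, and without treated replicate 3 the median was 0.92. Camera gave adjusted p = 1.8e-07 for neutrophil and 6.2e-07 for inflammatory genes, with adjusted p = 0.446 and 0.462 with an estimated correlation. Mast cell, basophil and eosinophil markers were positive in 8 of 10 with a median of 1.39 (adjusted p = 0.0253, and 0.446 with an estimated correlation), Cma1, a mast cell chymase, being the 1 that passed over the list alone with 1.00 ± 0.509 CPM against 0.188 ± 0.101. Hdc, which makes histamine, had 1.51, 4.83 and 19.9 CPM in treated replicates 1 to 3 and 0.920 ± 0.0957 in PBS libraries. With the adipocyte mean as a covariate this granulocyte call ended (median 1.04, adjusted p = 0.255), and it ended with halved counts (1.03, adjusted p = 0.0786).

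Macrophage lists were called higher with the preset correlation. General monocyte and macrophage markers were positive in 19 of 20 with a median of 0.35, 5 passing over the list alone. Csf1r, the growth factor receptor of the lineage (chromosome 18, 61105572 to 61132149), had 72.0 ± 9.24 CPM against 50.3 ± 4.11, a log2 fold change of 0.52 ± 0.10 (adjusted p = 0.166), and the Fc receptor gene Fcgr3 had 0.58 ± 0.11. All 15 genes of classical activation were positive with a median of 1.16, 2 passing over the list alone, Cd86, a costimulatory ligand, and Fpr2, a formyl peptide receptor (1.83 ± 0.49). Classical list means were 0.31, 1.43 and 1.76 in treated replicates 1 to 3, treated replicate 1 lying below PBS replicate 1 (0.36). Nos2, the inducible nitric oxide synthase, had 22.9, 76.8 and 119 CPM in treated replicates 1 to 3 and 15.8 ± 4.32 in PBS libraries, a log2 fold change of 2.21 ± 0.70 (adjusted p = 0.331). Genes of alternative activation were positive in 10 of 15 with a median of 0.52, and the 1 that passed over the list alone was lower: Vegfa, the main angiogenic growth factor, with 634 ± 36.9 CPM against 774 ± 50.4 and a log2 fold change of −0.29 ± 0.07. Il4ra had 0.55 ± 0.15, and Arg1, which consumes arginine, had 927 ± 244 CPM against 586 ± 114 and 0.66 ± 0.23 (adjusted p = 0.336). Camera gave adjusted p = 9.8e-06, 9.5e-07 and 0.0253 for general, classical and alternative genes, with adjusted p = 0.446, 0.446 and 0.524 with an estimated correlation. Over all genes tested 0 members passed. The alternative call was lost without PBS replicate 2 (median 0.43), PBS replicate 3 (0.26) or treated replicate 1 (0.30), and with either the adipocyte (0.24) or the muscle mean (0.28) as a covariate, and without treated replicate 2 the general median was 0.19.

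T cell and NK cell lists were called higher with the preset correlation, and 0 of their genes passed when adjusted over all genes tested. T cell markers were positive in 19 of 20 with a median of 0.41, and 2 passed over the list alone, among them Cd6 (0.70 ± 0.15). Cd4 had 14.97 ± 2.24 CPM against 8.81 ± 3.84, and Cd8a 7.09 ± 3.38 against 6.17 ± 0.946. Foxp3, the regulatory T cell factor, had 13.8 ± 0.698 against 14.7 ± 1.46. NK and cytotoxic genes were positive in 15 of 22 with a median of 0.31, and 3 passed over the list alone. The 7 negative members were Xcl1 (−0.39), Klrc2 (−0.26), Klrc1 (−0.17), Klrk1 (−0.11), Klrd1 (−0.08), Klrb1c (−0.06) and Klri2 (−0.015). Of the Klr receptor genes of this list only Klre1 was positive (0.45), so the list call does not hold for them as a set. Klrg1, placed in the naive and memory T cell list, was positive (1.25 ± 0.31). Prf1, which encodes perforin (chromosome 10, 61297836 to 61304263), had 8.22 ± 0.552 CPM against 4.87 ± 0.636, a log2 fold change of 0.75 ± 0.13 (adjusted p = 0.156). Ccl5, a T cell chemoattractant, had 3.91 ± 1.53 against 1.33 ± 0.0926, and Il2rb, the receptor chain shared by IL-2 and IL-15, 4.55 ± 0.546 against 3.08 ± 0.234. Gzmb had 17.7 ± 3.86 against 13.97 ± 2.68, Ifng 0.775 ± 0.140 against 0.536 ± 0.168, and the NK receptor gene Ncr1 0.545 ± 0.212 against 0.459 ± 0.189. Camera adjusted p-values were 2.7e-06 for T cell and 0.00202 for NK genes, and with an estimated correlation adjusted p = 0.481 and 0.446. The NK call was lost without treated replicate 1 (median 0.27, adjusted p = 0.125) and without both libraries numbered 1 (0.36, adjusted p = 0.0723), and without treated replicate 1 the log2 fold change of Cd8a turned to −0.25. T cell marker means were 0.59, 0.50 and 0.18 in treated replicates 1 to 3, where the muscle and adipocyte means given above also differed.

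**Figure D2:**
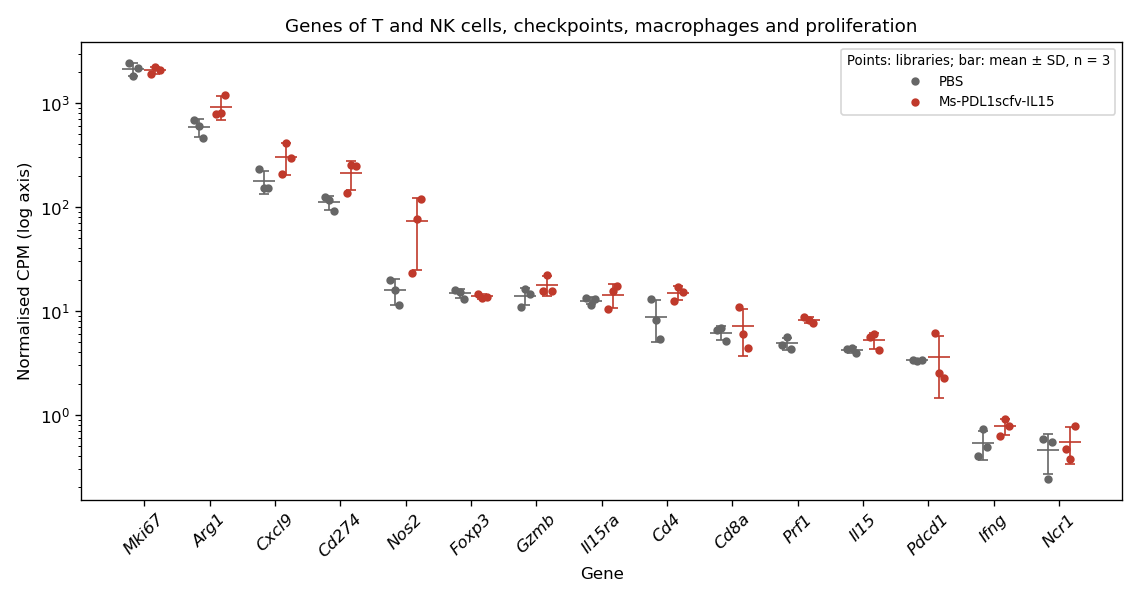
Normalised CPM on a log axis (vertical) of the 15 genes named in advance (horizontal), with 1 point per library, PBS in grey and Ms-PDL1scfv-IL15 in red, and the mean ± SD of 3 libraries as bars. Prf1 lay between 7.72 and 8.81 CPM in the treated libraries and between 4.31 and 5.56 in the PBS libraries, while Mki67 overlapped between the groups.

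Genes of the PD-L1 and IL-15 axes mostly had positive values, and 0 passed when adjusted over all genes tested. Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095), had 136, 255 and 246 CPM in treated replicates 1 to 3 and 111 ± 17.9 in PBS libraries (n = 3), a log2 fold change of 0.94 ± 0.28 (adjusted p = 0.30), every treated library lying above every PBS library. Its receptor gene Pdcd1 had 3.62 ± 2.16 against 3.37 ± 0.0377, and turned to −0.51 without treated replicate 1. Checkpoint genes were positive in 14 of 17 with a median of 0.23, and 2 passed over the list alone, Vsir, which encodes VISTA (0.48 ± 0.08), and Entpd1, the ectoenzyme CD39 (0.51 ± 0.10). The mouse gene Il15 had 5.24 ± 0.951 CPM against 4.21 ± 0.256, and Il15ra 14.4 ± 3.63 against 12.5 ± 0.990. Genes of IL-15 and common gamma chain signalling were positive in 15 of 19 with a median of 0.32, and 0 passed over the list alone, Il2rb having 0.56 ± 0.14 and Stat3 0.25 ± 0.09. Camera gave adjusted p = 0.00284 and 0.000817 for checkpoint and IL-15 genes, with adjusted p = 0.446 for both with an estimated correlation, and with the adipocyte mean as a covariate both calls ended (medians 0.36 and 0.093, adjusted p = 0.0560 and 0.166). The checkpoint median was 0.55 without PBS replicate 1, 0.12 without PBS replicate 3, and 0.35 and 0.36 without treated replicates 2 and 3.

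Lymphoid tissue genes included transcripts that were nearly absent from PBS libraries, and B cell genes were called higher with the preset correlation. Ccl21a, a chemokine that draws T cells and dendritic cells to lymphoid tissue (chromosome 4, 42772860 to 42773993), had 0 counts in every PBS library and 138, 72 and 40 in treated replicates 1 to 3, at least 38.9-fold higher over the groups (edgeR adjusted p = 0.0978), though reads can be shared between its near-identical copies. Lymphoid chemokine and high endothelial genes were positive in 9 of 10 with a median of 1.01, also with Ccl21a set to its bound, and 3 passed over the list alone, among them Bst1 (1.07 ± 0.20). B cell and plasma cell markers were positive in 10 of 11 with a median of 0.52, and the 1 that passed over the list alone was Ighm, the constant region of IgM, with 10.6 ± 1.18 CPM against 4.52 ± 1.81. Cd22 had 0.90 ± 0.39. Naive and memory T cell genes were positive in 12 of 18 with a median of 0.14, and 3 passed over the list alone, among them Klrg1 (1.25 ± 0.31) and Id3 (1.02 ± 0.28). Camera gave adjusted p = 7.9e-06, 0.0286 and 0.0212 for the 3 lists, with adjusted p = 0.446, 0.574 and 0.548 with an estimated correlation. The B cell call was lost without PBS replicate 3 (median 0.27) or treated replicate 2 (0.44), with the adipocyte mean as a covariate (0.02) and after removal of immunoglobulin and T cell receptor genes (adjusted p = 0.143), and its median was 0.91 without PBS replicate 1. The naive and memory call was lost without PBS replicate 3 (0.03), treated replicate 1 (0.15) or treated replicate 3 (0.09) and with either covariate, and its medians were 0.42 and 0.23 without PBS replicate 1 and treated replicate 2. Without PBS replicate 1 the lymphoid median was 1.56.

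Among stromal and tumour cell groups, vascular genes were the ones called. Endothelial genes were positive in 15 of 18 with a median of 0.31, and 0 passed over the list alone, Eng having 0.38 ± 0.11 and Cldn5, a tight junction protein of endothelium, 1.05 ± 0.33. Pericyte and smooth muscle markers were positive in 10 of 14 with a median of 0.83, and Lmod1, an actin nucleator of smooth muscle, passed over the list alone with 7.92 ± 2.05 CPM against 2.94 ± 0.842, while Myl9 had 1.20 ± 0.35. Camera gave adjusted p = 0.00354 and 0.0073, with adjusted p = 0.600 and 0.574 with an estimated correlation. The endothelial call was lost without PBS replicate 3 (median 0.16) or treated replicate 3 (0.04) and with the adipocyte covariate (0.10), and the pericyte call without treated replicate 1 (0.45) and with the adipocyte (0.44) or muscle covariate (0.48), its median being 0.54 without treated replicate 3.

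Proliferation and metabolism of the tumours gave no called list in the main test. Cell cycle genes had a median log2 fold change of 0.05 over 25 genes (camera adjusted p = 0.712), and Mki67, the proliferation antigen, had 2062 ± 159 CPM in treated and 2141 ± 302 in PBS libraries (n = 3). Medians were −0.01 for oxidative phosphorylation, 0.12 for hypoxia and glycolysis, 0.12 for p53 and apoptosis, and 0.04 for the unfolded protein response, whose mean was −0.01. Fibroblast and extracellular matrix genes had a median of 0.19, peripheral nerve markers 0.23, carcinoma epithelial markers 0.20 and keratinocyte markers 0.08. Genes of TGF-β and epithelial-mesenchymal transition had a median of −0.05 and a mean of 0.06, and immediate early and heat shock genes a median of 0.05 and a mean of −0.01. Dendritic cell markers had 0.03, regulatory T cell genes 0.04 and red blood cell genes 0.22. Camera adjusted p-values of these 14 lists lay between 0.165 and 0.845. Other settings could turn a call: without PBS replicate 1 dendritic (median 0.29) and regulatory T cell genes (0.47) were called higher, as were red blood cell genes without PBS replicate 3 (0.81) or treated replicate 2 (0.53) and with the replicate block (0.33). Without both libraries numbered 1 cell cycle (0.11, adjusted p = 0.0331) and dendritic cell genes (0.26) were called higher, while with the adipocyte mean as a covariate cell cycle (−0.089, adjusted p = 0.0096) and immediate early genes (−0.26, adjusted p = 0.0074) were called lower.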

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

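The covariate fits, the fit without both libraries numbered 1 and the halved counts were chosen after the data were seen. The count of 0 genes higher and 0 lower held with RLE, upper quartile and library size scaling, the stricter filter, non-robust dispersions, the 10 most abundant genes or the receptor genes removed, limma voom with and without sample weights, a minimum fold, halved counts and the adipocyte covariate. It did not hold with DESeq2 (531 higher, 142 lower; 418 and 97 on halved counts), without a filter (104 and 36), with the muscle covariate (46 and 4), or without both libraries numbered 1 (785 and 426), and over the libraries left out in turn it ran from 0 to 448 higher and from 0 to 210 lower, the high end being without treated replicate 1. Of the 59 named genes DESeq2 called 38, edgeR without treated replicate 1 called 31 and edgeR without a filter 16. Why the unfiltered fit called more genes was not tested. No scaling moved the median of all genes by more than 0.0169 on the log2 scale. The number of lists called higher was 18 to 25 over the libraries left out, and 0 with an estimated correlation or fry's directional test. It was 13 with the adipocyte covariate, which also gave 2 lists lower, cell cycle and immediate early genes. With the replicate block 0 genes were called and 24 lists were higher. No label says whether the replicate numbers pair the samples. The correlations of same-numbered deviations were 0.06, 0.04 and −0.10, and not every sample correlated best with its own number. These values gave no sign of pairing, but 3 libraries per group that differ in tissue content cannot exclude it. The mitochondrial difference of 0.137 percentage points lay between 0.0919 and 0.168 over libraries left out and at 0.145 without the 10 most abundant genes. Of the named genes' values under alternatives 1172 kept their direction and side of the threshold, 160 kept their direction and passed it, and 15 turned, in 5 genes. Of the 23 called lists' values 471 stayed, 77 lost the call and 2 turned, in skeletal muscle markers alone. Depth limits the genes near 0 counts, such as Ccl21a, whose fold over PBS libraries is bounded by a floor of 6 counts per group.

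The values that turned in sign follow, and the cause was not tested. Over the libraries left out, log2 fold changes ran from −0.51 to 0.37 for Pdcd1, −0.25 to 0.46 for Cd8a, −0.092 to 0.48 for Ncr1 and −0.16 to 0.043 for Mki67. List medians ran from −0.42 to 4.56 for skeletal muscle, −0.074 to 0.47 for regulatory T cell, −0.050 to 0.29 for dendritic cell, −0.048 to 0.10 for cell cycle, −0.097 to 0.19 for immediate early, −0.071 to 0.31 for peripheral nerve and −0.21 to 0.55 for carcinoma epithelial genes. Pdcd1 was −0.040 with the replicate block, −0.19 in voom with sample weights, −0.017 in voom, −0.36 with the muscle covariate and −0.50 without both libraries numbered 1. Cd8a was −0.12 and −0.21 in those last 2 fits, and Mki67 0.10 in the last. With the adipocyte covariate Il15ra was −0.16 and Ncr1 −0.10, and medians were −0.057 for dendritic cell, −0.033 for regulatory T cell, −0.089 for cell cycle, −0.0037 for p53, −0.26 for immediate early, −0.11 for carcinoma epithelial and −0.030 for keratinocyte genes. With the muscle covariate regulatory T cell genes were at −0.034 and muscle markers at −0.10. Oxidative phosphorylation genes were at 0.010 with library size alone, 0.013 with the stricter filter and 0.015 without both libraries numbered 1. Keratinocyte markers were at −0.24 without a filter, peripheral nerve markers at −0.047 in voom with sample weights, and regulatory T cell genes at −0.011 without shared members.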

Other observations

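The tests on muscle markers in 1 library and on leukocyte content in separate parts of the immune lists, and the genes named in the next 2 paragraphs, were chosen after the values were seen. Without treated replicate 1, the library rich in muscle transcripts, edgeR's quasi-likelihood test called 448 genes higher and 210 lower. The treated libraries left, replicates 2 and 3, had the highest adipocyte marker means (2.51 and 3.00, against 0.11 in treated replicate 1). This fit therefore cannot tell treatment from fat content. Among those higher were Lcn2, an iron-siderophore binding protein of neutrophils and inflamed tissue, with a log2 fold change of 5.92 ± 0.37 (SE, adjusted p = 0.000756), Saa3, an acute-phase protein (5.42 ± 0.55), Cxcr2, the neutrophil chemokine receptor (5.65 ± 0.83), and Csf2, which encodes GM-CSF (2.65 ± 0.39). Clec4e, the Mincle receptor for a mycobacterial cell wall glycolipid, had 2.39 ± 0.18 (adjusted p = 0.00198), Nos2 2.63 ± 0.32 and Acod1, which makes itaconate, 1.99 ± 0.23. Also higher were Fmo1 (2.79 ± 0.52) and Dgat2 (2.66 ± 0.38). Among those lower were the junction genes Jup (−1.05 ± 0.14) and Pkp1 (−0.89 ± 0.13), the basement membrane collagen gene Col4a5 (−1.32 ± 0.24) and the linker histone gene H1f0 (−0.90 ± 0.07). With all 6 libraries the adjusted p of these genes lay above the threshold, for example 0.259 for Lcn2 and 0.349 for Clec4e.

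Over all 6 libraries, 15 genes shared the smallest adjusted p of 0.0978, 12 with higher and 3 with lower values in treated tumours. Esm1, a proteoglycan secreted by angiogenic endothelium (chromosome 13, 113209659 to 113218098), had 7.28 ± 0.465 CPM in treated and 14.1 ± 0.973 in PBS libraries (SD, n = 3), and the transcriptional repressor gene Tcf7l1 11.2 ± 1.09 against 19.7 ± 1.38. Gm15401, annotated antisense within Tcf7l1, had −0.82 ± 0.12 against −0.81 ± 0.10 for Tcf7l1, and without a stated strand setting the reads of the pair cannot be assigned. Enpp2, which encodes autotaxin, had 5.44 ± 1.41 CPM against 1.59 ± 0.416, Lst1, a leukocyte transcript, 6.26 ± 1.00 against 2.97 ± 0.17, and Rspo3, a Wnt potentiator, 0.850 ± 0.359 against 0.0867 ± 0.0146.

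The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes at an unadjusted p under 0.05, 2 splits reached the number of the real one, 2518, the highest other being 2550. For lists called, 2 splits reached the real 23, the highest other also being 23. In both cases the other split set PBS replicate 1 with treated replicates 2 and 3 against the rest, the first 3 being the libraries with the highest adipocyte marker means. It differs from the real split by an exchange of the libraries numbered 1 and still sets treated replicates 2 and 3 against PBS replicates 2 and 3, a contrast that alone called 785 genes higher and 426 lower. Adipocyte means also differed in that contrast (2.51 and 3.00 against −0.76 and −0.73), so it cannot tell treatment from fat content.

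Immune and interferon lists were called higher in treated tumours with the preset correlation. With the adipocyte marker mean as a covariate 12 of the 19 called immune lists were still called with the preset correlation, with a median of their medians of 0.36 against 0.49 without it. The split above that set the libraries with the highest adipocyte means against the rest also called 23 lists. A marker mean may track fat content only in part, so this fit does not exclude fat tissue as the whole cause. With the muscle mean 17 were still called. The muscle mean mostly marks treated replicate 1 (5.36). There the type I interferon and inflammatory means were the lowest of the treated group (0.19 and 0.20), and the T cell mean the highest (0.59). For lists low in that library the muscle fit could not remove the rise, so no conclusion on muscle is drawn from it. Of the 7 lists lost with the adipocyte mean, medians fell in 5, B cell (0.52 to 0.017), IL-15 (0.32 to 0.093), MHC class II (0.38 to 0.11), alternative macrophage (0.52 to 0.24) and mast cell genes (1.39 to 1.04), where fat may account for part, while they rose for checkpoint (0.23 to 0.36) and naive and memory T cell genes (0.14 to 0.19). The adipocyte mean correlated with group at 0.63, so the fit splits a shared difference between them. With an estimated correlation 0 lists were called in either fit, as without a covariate. A rise of all leukocytes in equal proportion would move immune lists alike, and the neutrophil values argue against such an even rise. The neutrophil median lay 1.81 above that of 10 pan-leukocyte genes (0.42), and at least 1.12 above it without any 1 library. In all, 14 of 14 members lay above it, though spread widely (interquartile range 2.69). S100a8 had only 2, 10 and 2 counts in PBS replicates 1 to 3, so the size of such gaps is uncertain. A rise of neutrophils beyond that of other leukocytes is not covered by this comparison. Relative to PBS, the neutrophil mean less the pan-leukocyte mean was 1.15, 1.40 and 3.06 in treated replicates 1 to 3, against at most 0.41 in PBS libraries. For inflammatory genes an even rise of leukocytes cannot be told apart. Their median lay 1.5 above (interquartile range 1.63) but 0.48 without treated replicate 3. Their difference of means was −0.063 in treated replicate 1 against at most 0.11 in PBS libraries. For the other lists leukocyte content stays open: 14 of 17 medians lay within 0.3 of the pan-leukocyte median, type I interferon at 0.07 above and MHC class I at −0.16 from it, while classical macrophage (0.74), lymphoid (0.59) and mast cell (0.97) medians lay higher. The same window also held the medians of carcinoma epithelial (0.20) and fibroblast genes (0.19), so lying in it does not single out leukocyte content. A response to the treatment stays open as a hypothesis, untested here, and the splits above were too few to decide on chance. With PBS as the only other group, effects of the bacterium and of its immunocytokine cannot be told apart.

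Muscle transcripts in treated replicate 1 are consistent with muscle tissue taken with that tumour: 17 of 19 measured markers lay at least 2 on the log2 scale above every other library, Mb and Eno3 being the exceptions. Relative to total counts, Myh4, a fast myosin heavy chain, had 1096 CPM there and at most 10.1 elsewhere, and the 19 markers with Pvalb summed to 3329 CPM against 62.9 to 202. Reads shared between myosin or actin copies are not enough, since the 8 measured single-copy markers rose there by a median of 5.12 over the mean of the 5 other libraries. No biological explanation was tested.

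Ccl21a, at 0 counts in all PBS libraries, went with Mmrn1, a multimerin of lymphatic endothelium and platelets chosen after its values were seen, with 4, 0 and 0 counts in PBS and 110, 96 and 36 in treated replicates 1 to 3, a ratio of 56.5 (95% interval 15.3 to 472 from 121 and 2 fragments). Reads moving between Ccl21 copies do not account for this, since the 5 copies in the table together had 2 counts in all PBS libraries and at least 1.08 CPM in each treated library. Lymphatic vessels in or beside the treated samples may contribute. Of 8 other lymphatic markers tested 4 had a log2 fold change above 0.5 (Prox1 1.91, Reln 2.58, Sema3d 0.97, Fxyd6 1.48). Lyve1 (−0.25), Nrp2 (0.01), Flt4 (0.27) and Pdpn (0.32) did not. Other cells of the tumour may express markers of either set, which leaves the question open. Fxyd6 overlapped between the groups, treated replicates 2 and 3 (log2 CPM −1.73 and −2.03) lying below PBS replicate 1 (−1.56). Prox1 and Reln had few counts in PBS libraries (log2 CPM up to −2.67 and −3.37), so the size of their change is uncertain. Whether lymphatic vessels came with the treatment or with the tissue sampled was not tested.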
